A study of Mus musculus with 46 samples.

How the data were processed

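The deposited table held linear intensity for 28856 probe sets on 46 whole-transcript arrays, and the scaling the authors applied is not given in the sources used here. The submitters' processing notes name the mouse assembly mm9. Values ran from 16 to 27420 and no array had a minimum above 16.01. Whether a constant was added is not known, and log2 was taken with no further offset or scaling. Per the labels' protocols, feeder cells were removed by plating on gelatin before RNA was taken.

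Probe sets with 1 gene symbol (21789) were kept. Those with several symbols (1621) and those outside the annotation (5446) were left out, and for the 999 genes with more than 1 probe set the one with the highest mean was kept, which gave 19938 genes. Gene symbols were checked against 21698 genes of GRCm38.p6, and 0 were changed. Near-identical gene copies, such as those of Nxf2, Tuba3b and Mageb4, may share probes, which was not resolved. A background level was read from 1027 olfactory receptor genes, and 12749 genes had a mean above their 95th percentile of 161. Log2 differences from a group under that level are fitted values, not bounds, and a fold is then given as at least the brighter mean over that level.

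The 2 cultures of each line were averaged on the log2 scale, so that n counts lines. All 23 lines entered a single limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 15 residual degrees of freedom and 2.71 prior degrees of freedom). Benjamini-Hochberg adjustment was made within each comparison at 0.05, and p-values measure the spread between lines. Comparisons with the other induced routes set 3 lines against the equal-weighted means of the other 3 routes. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 19 lists of a comparison, and again with the correlation estimated from the data. Positions were compared with two-sided exact permutation tests.

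The comparisons, the gene lists and the choice of named genes were fixed before the data were examined. The text names members of the lists, in order of log2 fold change among those past the threshold and with members that go against a list's name, and the 4 targeted genes. Beyond these it names, from the top, the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes whose lines do not overlap. Lines fail to overlap by chance in 10% of genes for 3 lines against 3 and in 20% for 2 against 3. The lists and their measured members were naive pluripotency (28), spermatogonial stem and progenitor genes (30), germline, meiosis and piRNA genes (34), p53 targets (28), paternally (16) and maternally (15) expressed imprinted genes, DNA methylation genes (14), primed epiblast and mesendoderm (19), primitive endoderm (18), trophoblast (17), a 2-cell-like state (5), feeder and fibroblast genes (21), testis somatic cells (15), proliferation (21), G1 cyclins, inhibitors and Myc (16), GDNF and FGF signalling (23), glycolysis (17), Y-linked genes and Xist (6) and the targeted genes (4). Trp53 was not analysed here.

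Other ways of processing, also fixed in advance, took all 46 arrays as independent samples, modelled the line as a random block (statmod 1.5.0), fitted only the groups compared, applied quantile normalization, centred each array on its median, left out the 40% dimmest genes, used eBayes with a trend, averaged the probe sets of a gene, added culture or clone number as a block, and left out each line in turn. Those chosen after the data were seen left out culture 1 of Oct4 mGS 1, or added the feeder score of each line as a covariate.

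The pipeline was checked with 200 changed among 19938 simulated genes. At 1.5, 2 and 4-fold, it called 62.7%, 92.5% and 98.5% of them for Dnmt mGS against iPS, 38.8%, 85.1% and 98.5% for spontaneous mGS against iPS, and 67.2%, 98.5% and 100% for Sox2 mGS against the other routes. With no change simulated, 0 genes of limma passed for Dnmt mGS against iPS. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.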

Results

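Expression was measured on 46 whole-transcript arrays of 23 mouse cell lines, with 2 cultures of each line, in 8 groups. Germline stem cells (GS), spermatogonial stem cells grown in culture with GDNF and FGF2, gave 3 lines. The reference pluripotent cells were 3 lines of embryonic stem cells (ES: R1, B6-6 and BRC1) and 3 lines of induced pluripotent stem cells (iPS 1, 2 and 5) made with retroviral Oct4, Sox2, Klf4 and c-myc. Multipotent germline stem cells (mGS) are cells with an ES-like growth habit that arise from GS cultures. Of these, 2 lines arose spontaneously, and 12 lines came from lentiviral treatment of GS cells in 4 routes of 3 lines each: knockdown of Dnmt1 and p53 (Dnmt mGS), knockdown of Dmrt1 and p53 (Dmrt mGS), Sox2 with p53 knockdown (Sox2 mGS) and Oct4 with p53 knockdown (Oct4 mGS). Array medians lay between 215.4 and 242.5 intensity units, apart from culture 1 of Oct4 mGS 1 at 264.8. Values ran from 16 to 27420, and the 1027 olfactory receptor genes, which these cells are not known to use, had a median of 64.9 and a 95th percentile of 161, the background level. Differences are given as log2 of the first group over the second, ± limma's standard error, with intensities in parentheses, and n is 3 lines per group except for spontaneous mGS, with 2. Unless stated otherwise, a gene that rose or fell passed limma's adjusted p of 0.05. List counts adjusted over the list alone stand beside the counts over all genes where they differ, and were otherwise equal.

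The 4 genes targeted by the routes were read first, to show how far each route left its target changed. Dnmt1, the maintenance DNA methyltransferase, averaged 1030 in Dnmt mGS against 3030 in GS (−1.55 ± 0.35, adjusted p = 0.0012) and 2170 in the other induced routes (−1.07 ± 0.28, adjusted p = 0.018). Its level was 620 in Dnmt mGS 1 and 647 in Dnmt mGS 3, and 2750 in the line labelled Dnmt mGS 2, within the 1930 to 2770 of the 9 lines of the other routes. The fall against the other routes lost its call without Dnmt mGS 1 (−0.70) or Dnmt mGS 3 (−0.73) and was −1.77 without Dnmt mGS 2. Differences from ES (−1.07, adjusted p = 0.053) and iPS (−1.02, adjusted p = 0.084) did not pass, but did without Dnmt mGS 2 (−1.78 and −1.73). Dmrt1, a transcription factor that keeps germ cells from taking a pluripotent course, was high in GS. It read 3650 in GS and 207 to 432 in the other group means, higher in GS than in ES by 3.08 ± 0.42 and than in iPS by 3.46 ± 0.42. In Dmrt mGS it was below GS (−3.37 ± 0.42), but it was not called different from iPS (0.09, adjusted p = 0.92) or from the other routes (0.36, adjusted p = 0.8).

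Sox2 and Pou5f1 (Oct4), core transcription factors of pluripotency, were lower in GS than in ES (−2.85 ± 0.45 and −3.03 ± 0.24). Sox2 fell in Sox2 mGS, the route that received a Sox2 virus, to 1290 against 4330 in iPS (−1.75 ± 0.45, adjusted p = 0.011), with like falls against ES (−1.65 ± 0.45), mGS (−1.70 ± 0.51) and the other routes (−1.50 ± 0.37, adjusted p = 0.015). All 3 Sox2 mGS lines read 1250 to 1300, while the lines outside GS, Oct4 mGS and Sox2 mGS read 3660 to 5540. The call against ES was lost without ES R1 (−1.54), Sox2 mGS 1 (−1.63), Sox2 mGS 2 (−1.66) or Sox2 mGS 3 (−1.66). The call against mGS was lost without any 1 line of mGS or Sox2 mGS (−1.83 to −1.58). That against the other routes was lost without any 1 Sox2 mGS line (−1.51 to −1.48). Over GS, Sox2 rose by 1.2 ± 0.45, and by 2.05 without GS 1. The call was lost without GS 2 (0.82), GS 3 (0.73) or any 1 Sox2 mGS line (1.19 to 1.22). Oct4 mGS had 2510 of Sox2, above GS by 2.17 ± 0.45. Pou5f1 averaged 4840 in Oct4 mGS, with no call against iPS (−0.03, adjusted p = 0.95) or the other routes (−0.05, adjusted p = 0.92). Within GS, Sox2 was 1810, 331 and 293 and Pou5f1 1000, 365 and 381 in lines 1, 2 and 3. Whether the probes read the viral transcripts is not given in the sources used here.

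**Figure D1:**
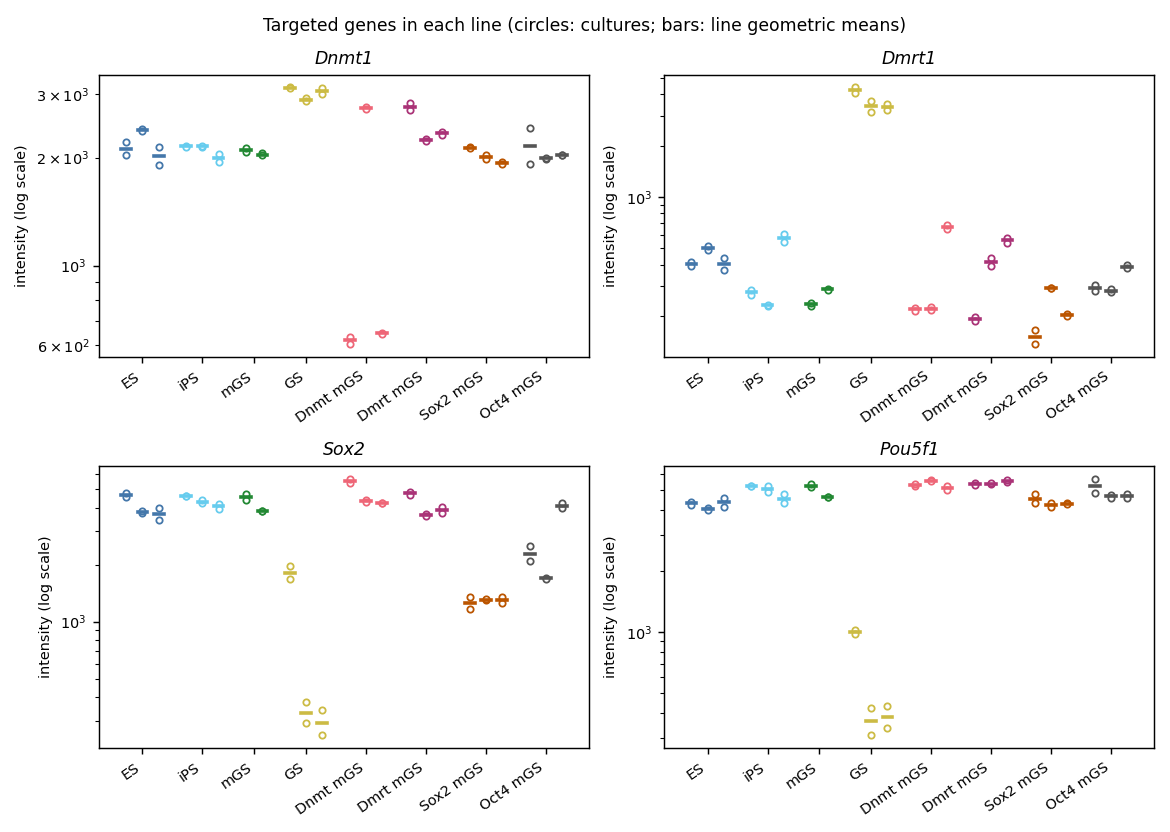
Intensity (log axis) of Dnmt1, Dmrt1, Sox2 and Pou5f1 in each of the 23 lines, with circles for the 2 cultures of a line and bars for the geometric mean of the line. Dnmt1 was 620 and 647 in Dnmt mGS 1 and 3 but 2750 in Dnmt mGS 2, and Sox2 was 1250 to 1300 in the 3 Sox2 mGS lines.

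GS cells were compared with ES cells to describe what separates cultured germline cells from pluripotent ones. Nxf2, an X-linked mRNA export factor gene, was at least 92.4-fold higher in GS (6.85 ± 0.22, 14900 against 129), and the tubulin gene Tuba3b was higher by 6.65 ± 0.43 (8880 against 88.6). Zbtb16, which encodes the spermatogonial factor PLZF, was higher by 6.51 ± 0.13 (11600 against 128) and the X-linked Mageb4 by 6.42 ± 0.16 (9170 against 107). Nanog, a core gene of the ES network, was at least 32.1-fold lower (−6.77 ± 0.22, 47.3 against 5160). The nuclear receptor gene Nr0b1 (−6.79 ± 0.64, 38.7 against 4280), the Nodal co-receptor gene Tdgf1 (−6.71 ± 0.27, 51.7 against 5430) and the ES growth factor gene Fgf4 (−5.37 ± 0.36, 75.9 against 3130) were also lower. Of the 19938 genes, 8611 passed, 5174 higher and 3437 lower in GS. All ES lines differ from the others in strain, and GS cells grew in another medium than the pluripotent lines, so neither can be separated from cell type here.

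Between GS and ES, among 28 measured naive pluripotency genes 1 rose, 24 fell and 3 did not pass (adjusted p = 2.1e-16, or 0.018 with an estimated correlation), and the exception was the signal transducer Stat3 (0.80 ± 0.16). The list of spermatogonial stem and progenitor genes rose: 21 rose, 2 fell and 7 did not pass (adjusted p = 3.5e-07, or 0.0058 with an estimated correlation), with Zbtb16, the GDNF receptor gene Ret (4.91 ± 0.18, 4090 against 136) and the RNA-binding Nanos3 (3.90 ± 0.17) at the top. Against its name, the stem cell factor receptor Kit (−1.86 ± 0.46) and the transcription factor Etv5 (−1.40 ± 0.32, and −0.77 without GS 1) were lower in GS. Genes of meiosis and the piRNA pathway rose together: 29 rose, 0 fell and 5 did not pass (adjusted p = 7.2e-17, or 0.013 with an estimated correlation), with Mageb4, the piRNA factor Asz1 (5.64 ± 0.35) and Taf7l (5.63 ± 0.14). Glycolysis genes were lower: 0 rose, 14 fell and 3 did not pass (adjusted p = 1.3e-08, or 0.024 with an estimated correlation). Pfkl differed by −3.89 ± 0.34 (100 against 1490) and Pgk1 by −3.21 ± 0.32. Targets of p53 were lower as well: 1 rose, 17 fell and 10 did not pass (adjusted p = 6.5e-06, or 0.25 with an estimated correlation). Psrc1 differed by −3.22 ± 0.36 and Eda2r by −3.19 ± 0.42, while Sesn1 rose (0.91 ± 0.19).

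Several further lists were lower in GS than in ES, though each lost its call with an estimated correlation. Feeder and fibroblast genes were among them (median −0.94, adjusted p = 0.046, or 0.68 with an estimated correlation), and their mean intensity, used as a feeder score, was 310 in GS and 585 in ES, with 626 in GS 1 and 310 in ES R1. Genes of DNA methylation and demethylation were split: 2 rose, 6 fell and 6 did not pass (adjusted p = 0.034, or 0.075 with an estimated correlation). The 5-methylcytosine dioxygenase Tet1 differed by −5.22 ± 0.16 and Dnmt3l by −4.63 ± 0.29, against rises of Tet3 (1.49 ± 0.12) and Mbd2 (1.27 ± 0.20). Genes of the primed epiblast and early mesendoderm fell: 2 rose, 8 fell and 9 did not pass (2 rose and 9 fell adjusted over the list alone, adjusted p = 0.0011, or 0.25 with an estimated correlation). Otx2 differed by −4.75 ± 0.39 and Cldn6 by −4.41 ± 0.39. For proliferation genes, 3 rose, 11 fell and 7 did not pass (3 rose and 12 fell adjusted over the list alone, adjusted p = 0.0035, or 0.25 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 differed by −2.33 ± 0.19 and Cdk1 by −1.06 ± 0.12. G1 cyclins, their inhibitors and Myc were lower: 2 rose, 6 fell and 8 did not pass (3 rose and 7 fell adjusted over the list alone, adjusted p = 0.046, or 0.25 with an estimated correlation, adjusted p = 0.14 with the feeder score fitted). Myc differed by −2.79 ± 1.04 and Ccne1 by −2.71 ± 0.16. Maternally expressed imprinted genes fell: 2 rose, 4 fell and 9 did not pass (adjusted p = 0.046, or 0.25 with an estimated correlation, adjusted p = 0.14 with the feeder score fitted). Meg3 differed by −2.61 ± 0.51 and Grb10 by −2.32 ± 0.62. The call of Myc was lost without ES B6-6 (−2.63), ES BRC1 (−2.49), GS 2 (−2.64) or GS 3 (−2.56).

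Against iPS cells, which share their strain label, GS cells showed the same named contrasts. Nxf2 was higher by 7.02 ± 0.22, Mageb4 by 7.01 ± 0.16 and Zbtb16 by 6.60 ± 0.13. Tdgf1 (−7.01 ± 0.27), Nr0b1 (−6.88 ± 0.64) and Nanog (−6.82 ± 0.22) were lower. In all 10769 genes passed, 7076 higher and 3693 lower in GS (4712 higher and 4091 lower with each array centred on its median), and the median of all genes was 0.166 higher in GS. Of naive genes 1 rose, 24 fell and 3 did not pass (adjusted p = 5.8e-16, or 0.014 with an estimated correlation). Of spermatogonial genes 24 rose, 2 fell and 4 did not pass (adjusted p = 2.7e-06, or 0.012 with an estimated correlation). Of germline genes 30 rose, 0 fell and 4 did not pass (adjusted p = 6.3e-16, or 0.013 with an estimated correlation). Among p53 targets 1 rose, 19 fell and 8 did not pass (adjusted p = 8.3e-08, or 0.16 with an estimated correlation). The apoptosis gene Perp differed by −3.87 ± 0.59 and Psrc1 by −3.64 ± 0.36. Glycolysis genes fell: 0 rose, 14 fell and 3 did not pass (adjusted p = 8.5e-11, or 0.013 with an estimated correlation). Pfkl differed by −4.51 ± 0.34 and Pgk1 by −3.62 ± 0.32.

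The reference pluripotent groups, iPS and ES, were compared to set a scale for the induced lines. They differed in few genes. The calcium-activated potassium channel gene Kcnma1 was at least 4.17-fold higher in iPS (4.30 ± 0.31, 671 against 34.1, adjusted p = 6.4e-07), the ubiquitin ligase gene Mid1 was 14.3-fold higher (3.84 ± 0.49, 3820 against 266), and neuropeptide Npy rose by 2.26 ± 0.43 (695 against 145). The Y-linked histone demethylase gene Kdm5d (−2.54 ± 0.39, 188 against 1090), Stard3nl (−2.53 ± 0.32, 137 against 790) and the protease inhibitor gene Serpina3n (−2.50 ± 0.56, 98.4 against 555) were lower. In all 125 genes passed, 58 higher and 67 lower in iPS (65 higher and 48 lower with each array centred on its median), against 2576 at an unadjusted p under 0.05. Without ES R1 the count was 900, without ES B6-6 78, without ES BRC1 55, without iPS 1 40, without iPS 2 45, without iPS 5 55 and with only the groups compared 22. Npy lost its call without ES B6-6 (2.25), ES BRC1 (2.24), iPS 2 (1.78) or iPS 5 (2.37). Serpina3n lost its call without ES B6-6 (−2.11), ES BRC1 (−1.82), iPS 1 (−2.33), iPS 2 (−2.50) or iPS 5 (−2.67).

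As lists, glycolysis genes (adjusted p = 7.1e-05, or 0.43 with an estimated correlation) and p53 targets (adjusted p = 0.00037, or 0.53 with an estimated correlation) were higher in iPS than in ES with no member past the test over all genes. Glycolysis genes averaged 2930 in ES R1, within the 2850 to 3150 of iPS. Trophoblast genes were higher too (adjusted p = 0.038, or 0.53 with an estimated correlation, adjusted p = 0.059 with the feeder score fitted), with 4 that rose adjusted over the list alone. Over all genes the 1 that rose was the transcription factor gene Ascl2 (1.08 ± 0.24). Ascl2 lost its call without ES B6-6 (1.03), ES BRC1 (0.89), iPS 1 (1.13), iPS 2 (1.15) or iPS 5 (0.96). Feeder and fibroblast genes, markers of the embryonic fibroblasts on which all lines grew, were lower in iPS (median −1.0, adjusted p = 0.0031, or 0.58 with an estimated correlation), with feeder scores of 292 in iPS and 585 in ES.

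All 5 mGS types were compared with GS, the cells they came from, to describe the change on conversion. Nanog was higher by 6.60 ± 0.25 in spontaneous mGS, 7.09 ± 0.22 in Dnmt mGS, 6.61 ± 0.22 in Dmrt mGS, 6.21 ± 0.22 in Sox2 mGS and 6.58 ± 0.22 in Oct4 mGS. Tdgf1 was higher by 6.90, 6.38, 6.46, 6.62 and 6.58. Mageb4 was lower in each (−6.95 ± 0.18, −6.72 ± 0.16, −6.90 ± 0.16, −6.93 ± 0.16 and −7.15 ± 0.16). The numbers of genes that passed were 8592 in mGS (3231 higher and 5361 lower), 9797 in Dnmt mGS (3814 and 5983), 8303 in Dmrt mGS (3506 and 4797), 8776 in Sox2 mGS (3862 and 4914) and 8545 in Oct4 mGS (4031 and 4514). The median of all genes was −0.13 in mGS and −0.126 in Dnmt mGS.

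Among 28 naive pluripotency genes, 23 rose and 1 fell (24 and 1 adjusted over the list alone) in mGS, 24 rose and 1 fell in Dnmt mGS, 21 rose and 1 fell in Dmrt mGS, 18 rose and 3 fell (19 and 3 adjusted over the list alone) in Sox2 mGS and 17 rose and 2 fell (18 and 2 adjusted over the list alone) in Oct4 mGS. Adjusted p was 1.6e-16, 1.2e-14, 8.9e-14, 1.5e-09 and 5.8e-10 in that order, or 0.013, 0.024, 0.025, 0.08 and 0.071 with an estimated correlation. Stat3 was lower than in GS in all 5 types (−0.77, −1.24, −1.42, −0.82 and −1.05), in mGS with its call lost without mGS 2 (−0.49). The nuclear receptor gene Nr5a2 was lower in Sox2 mGS (−2.35 ± 0.66), with its call lost without Sox2 mGS 2 (−1.63). Of 30 spermatogonial genes, 2 rose and 19 fell (3 and 19 adjusted over the list alone) in mGS, 2 rose and 25 fell in Dnmt mGS, 2 rose and 22 fell (2 and 24 adjusted over the list alone) in Dmrt mGS, 2 rose and 20 fell (2 and 21 adjusted over the list alone) in Sox2 mGS and 2 rose and 23 fell (3 and 23 adjusted over the list alone) in Oct4 mGS. Adjusted p was 2.1e-06, 2e-08, 1.3e-08, 1.2e-07 and 2.1e-09, or 0.0063, 0.0025, 0.0022, 0.0038 and 0.0013 with an estimated correlation. Zbtb16 differed by −6.52 in mGS and −6.37 in Oct4 mGS. Of 34 germline genes, 0 rose and 32 fell in mGS, 0 rose and 27 fell (0 and 29 adjusted over the list alone) in Dnmt mGS, 0 rose and 29 fell in Dmrt mGS, 0 rose and 32 fell in Sox2 mGS and 0 rose and 30 fell (0 and 31 adjusted over the list alone) in Oct4 mGS. Adjusted p was 6.5e-20, 5.5e-14, 6.1e-18, 1.1e-21 and 4.6e-22, or 0.0063, 0.024, 0.0099, 0.0043 and 0.004 with an estimated correlation. Of 17 glycolysis genes, 14 rose and 0 fell in mGS, 15 rose and 0 fell in Dnmt mGS, 14 rose and 0 fell (14 and 1 adjusted over the list alone) in Dmrt mGS, 11 rose and 0 fell in Sox2 mGS and 13 rose and 0 fell (14 and 0 adjusted over the list alone) in Oct4 mGS. Adjusted p was 3.1e-10, 1.4e-08, 9.5e-09, 5.7e-07 and 2.1e-08, or 0.013, 0.024, 0.025, 0.069 and 0.037 with an estimated correlation, and Pfkl was higher by 4.27 in mGS and 4.42 in Oct4 mGS. Targets of p53 were higher than in GS, although 4 of the 5 types carried a p53 knockdown vector: 19 rose and 1 fell in mGS, 15 rose and 3 fell (16 and 3 adjusted over the list alone) in Dnmt mGS, 15 rose and 2 fell in Dmrt mGS, 16 rose and 1 fell in Sox2 mGS and 15 rose and 2 fell (16 and 2 adjusted over the list alone) in Oct4 mGS. Adjusted p was 1e-07, 0.0013, 0.00045, 4.5e-06 and 0.00071, or 0.14, 0.38, 0.36, 0.23 and 0.35 with an estimated correlation. Mdm2, the ubiquitin ligase that p53 itself induces, fell in Dnmt mGS (−1.04 ± 0.26).

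Of 19 genes of the primed epiblast, 11 rose and 2 fell (13 and 2 adjusted over the list alone) in mGS, 8 rose and 3 fell in Dnmt mGS, 9 rose and 2 fell (10 and 2 adjusted over the list alone) in Dmrt mGS, 10 rose and 1 fell (11 and 1 adjusted over the list alone) in Sox2 mGS and 13 rose and 1 fell in Oct4 mGS. Adjusted p was 3.1e-06, 0.004, 0.00049, 5.6e-05 and 2.9e-05, or 0.14, 0.38, 0.3, 0.23 and 0.2 with an estimated correlation, and Otx2 was higher by 5.91 ± 0.39 in Sox2 mGS and 5.96 ± 0.39 in Oct4 mGS. Feeder and fibroblast genes rose over GS in Sox2 mGS: 15 rose, 0 fell and 6 did not pass (18 rose and 0 fell adjusted over the list alone, adjusted p = 5.6e-05, or 0.42 with an estimated correlation). The cadherin gene Cdh11 was higher by 3.65 ± 1.17, a call lost without GS 2 (3.23) or GS 3 (3.07), and Thy1 by 3.46 ± 0.71. They also rose in Oct4 mGS: 4 rose, 0 fell and 17 did not pass (2 rose and 0 fell adjusted over the list alone, adjusted p = 0.0096, or 0.63 with an estimated correlation). The matrix protein gene Lum was higher there by 2.81 ± 0.87, a call lost without GS 3 (2.55) or Oct4 mGS 1 (2.44), and Thy1 by 2.78 ± 0.71. Feeder scores were 310 in GS, with 626 in GS 1, 1490 in Sox2 mGS and 921 in Oct4 mGS, with 542 in line 3.

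Spontaneous mGS lines were compared with ES and iPS to show how near cells that arose without a vector came to each. Kcnma1 was higher than in ES (4.36 ± 0.34, 699 against 34.1), as was Npy (3.23 ± 0.48, 1350 against 145). Kdm5d (−2.73 ± 0.44, 164 against 1090) and Stard3nl (−2.63 ± 0.36, 128 against 790) were lower. In all 41 genes passed, 17 higher and 24 lower in mGS. Without ES R1 the count was 202, without mGS 1 21, without mGS 2 14 and with only the groups compared 2. Npy lost its call without mGS 2 (2.63), Kdm5d without mGS 1 (−2.68) or mGS 2 (−2.79) and Stard3nl without mGS 1 (−2.03). Germline genes were lower than in ES as a list (median −0.51, adjusted p = 1.6e-05, or 0.2 with an estimated correlation), and so were the genes of the Y chromosome and Xist (median −2.52, adjusted p = 3.2e-05, or 0.065 with an estimated correlation), whose mean was 86.2 in mGS 1, 357 in mGS 2 and 630 to 830 in ES. In each of these, 1 member fell over all genes, and 3 germline and 4 Y-linked genes fell adjusted over the list alone. Against iPS, 0 genes passed limma's adjusted p of 0.05, and 225 had an unadjusted p under 0.05. Germline genes were lower as a list (median −0.11, adjusted p = 0.00023, or 0.25 with an estimated correlation), with 162 and 167 in mGS and 155 to 222 in iPS. Feeder scores were 445 in mGS (247 in mGS 1 and 804 in mGS 2) and 292 in iPS.

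Dnmt mGS lines were compared with ES, iPS and spontaneous mGS to show what the Dnmt1 route left different from other pluripotent lines. Against ES, Kcnma1 was higher by 3.12 ± 0.31 (296 against 34.1), as in iPS and mGS. The Y-linked translation factor gene Eif2s3y was lower (−4.68 ± 0.95, 47.7 against 1220), as in mGS 1. Germline genes rose over ES: 6 rose, 1 fell and 27 did not pass (adjusted p = 0.021, or 0.72 with an estimated correlation). The piRNA factor gene Mael was higher by 2.75 ± 0.35 (4330 against 644), and the germ cell ADP/ATP carrier gene Slc25a31 by 2.06 ± 0.32. GDNF and FGF signalling genes fell: 1 rose, 3 fell and 19 did not pass (2 rose and 8 fell adjusted over the list alone, adjusted p = 0.021, or 0.72 with an estimated correlation, adjusted p = 0.054 with the feeder score fitted). They averaged 592 in Dnmt mGS 3 and 582 in ES R1. The immediate-early gene Egr2 (−1.64 ± 0.25, 119 against 370) and Fgfr2 (−1.37 ± 0.22) were lower. In all 2263 genes passed, 1350 higher and 913 lower (838 higher and 1136 lower with each array centred on its median). Without ES B6-6 the count was 1247, without ES BRC1 1083, without Dnmt mGS 1 1002, without Dnmt mGS 2 1336 and with only the groups compared 330.

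Against iPS, the T cell receptor subunit gene Cd3g was higher in Dnmt mGS by 3.86 ± 0.99 (789 against 54.3), and Eif2s3y was lower (−4.61 ± 0.95, 47.7 against 1160). Germline genes rose: 10 rose, 1 fell and 23 did not pass (15 rose and 2 fell adjusted over the list alone, adjusted p = 1.1e-05, or 0.22 with an estimated correlation). The meiotic cohesin gene Smc1b was higher by 2.83 ± 0.73 (664 against 93.4), and Slc25a31 by 2.31 ± 0.32 (605 against 122). Targets of p53 fell: 0 rose, 5 fell and 23 did not pass (1 rose and 14 fell adjusted over the list alone, adjusted p = 1.6e-07, or 0.22 with an estimated correlation). They averaged 484, 563 and 875 in Dnmt mGS 1, 2 and 3 and 862 to 1050 in iPS. The apoptosis gene Perp (−2.39 ± 0.59, 309 against 1620) and the kinase gene Plk2 (−2.25 ± 0.50, 340 against 1620) were lower. Genes of GDNF and FGF signalling fell: 1 rose, 5 fell and 17 did not pass (2 rose and 6 fell adjusted over the list alone, adjusted p = 1.1e-05, or 0.22 with an estimated correlation). Fos (−2.25 ± 0.58, 281 against 1340) and Egr2 (−1.88 ± 0.25, 119 against 437) were lower. In all 1369 genes passed, 834 higher and 535 lower (539 higher and 678 lower after quantile normalization and 392 higher and 905 lower with each array centred on its median). Without iPS 1 the count was 507, without iPS 2 279, without iPS 5 788, without Dnmt mGS 1 358, without Dnmt mGS 2 761 and with only the groups compared 881. Cd3g lost its call without iPS 1 (3.99), iPS 2 (3.84), iPS 5 (3.76), Dnmt mGS 1 (3.23) or Dnmt mGS 2 (3.24), and Eif2s3y without Dnmt mGS 1 (−4.30). Smc1b lost its call without iPS 1 (3.07), iPS 2 (2.35), Dnmt mGS 1 (2.74) or Dnmt mGS 2 (2.84). Perp lost its call without iPS 2 (−2.34), iPS 5 (−2.21), Dnmt mGS 1 (−2.24) or Dnmt mGS 2 (−1.80), and Plk2 without iPS 2 (−2.12), Dnmt mGS 1 (−1.87) or Dnmt mGS 2 (−1.99). Fos lost its call (−2.44 to −1.94) without any 1 iPS line, Dnmt mGS 1 or Dnmt mGS 2.

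Against spontaneous mGS, Smc1b was higher in Dnmt mGS by 3.52 ± 0.82 (664 against 57.8), and Npy was lower (−2.87 ± 0.48, 185 against 1350). Germline genes rose: 10 rose, 1 fell and 23 did not pass (16 rose and 2 fell adjusted over the list alone, adjusted p = 1.6e-09, or 0.16 with an estimated correlation). Slc25a31 was higher by 2.91 ± 0.36. Signalling genes of GDNF and FGF fell: 0 rose, 3 fell and 20 did not pass (2 rose and 6 fell adjusted over the list alone, adjusted p = 1.9e-06, or 0.16 with an estimated correlation). The phosphatase gene Dusp4 (−2.19 ± 0.48) and Egr2 (−2.05 ± 0.28) were lower. Feeder scores were 414 in Dnmt mGS, from 179 in line 2 to 1180 in line 3, and 247 and 804 in mGS 1 and 2. In all 544 genes passed, 354 higher and 190 lower (254 higher and 305 lower after quantile normalization and 171 higher and 250 lower with each array centred on its median). Without mGS 1 the count was 29, without mGS 2 150, without Dnmt mGS 1 98, without Dnmt mGS 2 289, without Dnmt mGS 3 1109 and with only the groups compared 4. Smc1b lost its call without mGS 1 (3.40), mGS 2 (3.64), Dnmt mGS 1 (3.43) or Dnmt mGS 2 (3.53), and Npy without mGS 2 (−2.27). Dusp4 lost its call without mGS 1 (−2.51), mGS 2 (−1.87), Dnmt mGS 1 (−1.76) or Dnmt mGS 2 (−2.20).

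Dmrt mGS lines were compared with the same 3 references to show what the Dmrt1 route left different. Kcnma1 was higher than in ES by 3.91 ± 0.31 (513 against 34.1) and Mael by 2.03 ± 0.35 (2630 against 644). Slc27a2 (−2.28 ± 0.25) and Stard3nl (−2.28 ± 0.32) were lower. Kcnma1 and Stard3nl differed from ES in iPS and vector-free mGS as well, so neither is particular to a route. In all 929 genes passed, 456 higher and 473 lower (229 higher and 653 lower with each array centred on its median), and none of the 19 lists passed. Against ES, without ES B6-6 the count was 593, without ES BRC1 308, without Dmrt mGS 1 512, without Dmrt mGS 3 479 and with only the groups compared 0 (2486 at an unadjusted p under 0.05). Set against iPS, Dmrt mGS had more of Fam120c, by 1.37 ± 0.22 (227 against 88), and less of Mid1 (−3.74 ± 0.49, 285 against 3820). Mid1 was lower in ES than in iPS as well. Targets of p53 were lower as a list (median −0.42, adjusted p = 3.4e-08, or 0.35 with an estimated correlation), at 544, 777 and 794 in Dmrt mGS 1, 2 and 3 and 862 to 1050 in iPS. GDNF and FGF signalling genes were lower too (median −0.36, adjusted p = 7.9e-05, or 0.35 with an estimated correlation), at 341, 652 and 626 against 681 to 714, and Egr2 fell (−1.10 ± 0.25). In all 169 genes passed, 71 higher and 98 lower (71 higher and 157 lower after quantile normalization and 33 higher and 318 lower with each array centred on its median). Against iPS, without iPS 1 the count was 17, without iPS 2 25, without iPS 5 99, without Dmrt mGS 1 57, without Dmrt mGS 2 106, without Dmrt mGS 3 65 and with only the groups compared 7. Fam120c lost its call without iPS 1 (1.36) or iPS 2 (1.29). Egr2 lost its call without iPS 1 (−1.16), iPS 2 (−0.97), iPS 5 (−1.15), Dmrt mGS 1 (−0.77) or Dmrt mGS 3 (−1.04).

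Dmrt mGS and spontaneous mGS differed in 13 genes, 4 higher and 9 lower in Dmrt mGS. The meiotic histone reader gene Zcwpw1 was higher by 1.82 ± 0.29 (847 against 240), and the DNA repair gene Xrcc5, which encodes Ku80, was lower (−1.62 ± 0.22, 789 against 2420). As lists, p53 targets (median −0.40, adjusted p = 1.3e-08, or 0.22 with an estimated correlation) and GDNF and FGF signalling genes (median −0.50, adjusted p = 4.9e-07, or 0.2 with an estimated correlation) were lower. Germline genes were higher (median 0.46, adjusted p = 3.3e-05, or 0.22 with an estimated correlation), with 6 that rose and 1 that fell adjusted over the list alone. Dmrt mGS 1 stood apart, at 544 in p53 targets, 341 in GDNF and FGF signalling genes and 280 in germline genes (211 and 218 in Dmrt mGS 2 and 3), and with a feeder score of 182 (918 and 770). Over all genes, 0 members of these lists passed limma's adjusted p. Without mGS 1 the count was 5, without Dmrt mGS 1 0, without Dmrt mGS 2 1, without Dmrt mGS 3 8 and with only the groups compared 0 (1234 at an unadjusted p under 0.05). Zcwpw1 lost its call without mGS 1 (1.59), mGS 2 (2.05), Dmrt mGS 1 (1.54) or Dmrt mGS 2 (1.96), and Xrcc5 without mGS 1 (−1.51), Dmrt mGS 1 (−1.66) or Dmrt mGS 2 (−1.51).

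Sox2 mGS lines were compared with ES, iPS and spontaneous mGS to show what the Sox2 route left different. Against ES, the R-spondin receptor gene Lgr5 was higher by 4.95 ± 0.61 (3530 against 115). The Y-linked zinc finger gene Zfy1 was lower (−4.35 ± 1.05, 24.8 against 505), and low in Dnmt mGS too. Naive genes fell: 0 rose, 11 fell and 17 did not pass (0 rose and 14 fell adjusted over the list alone, adjusted p = 1.6e-06, or 0.38 with an estimated correlation). The orphan nuclear receptor genes Esrrb (−2.76 ± 0.72, 359 against 2420) and Nr5a2 (−2.73 ± 0.66) were lower. Feeder genes were higher (median 1.37, adjusted p = 0.0019, or 0.69 with an estimated correlation), with 1 member that rose, the collagen cross-linking enzyme gene Lox (2.62 ± 0.68), and feeder scores of 1490 against 585. In all 2948 genes passed, 1586 higher and 1362 lower (1338 higher and 1820 lower after quantile normalization and 955 higher and 2237 lower with each array centred on its median). Without Sox2 mGS 2 the count was 1916 and without Sox2 mGS 3 1433. Zfy1 lost its call without ES R1 (−3.76). Esrrb lost its call without ES R1 (−2.68), Sox2 mGS 2 (−2.01) or Sox2 mGS 3 (−2.68), Nr5a2 without Sox2 mGS 2 (−2.01) and Lox without Sox2 mGS 3 (2.53).

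Against iPS, Lgr5 was at least 21.9-fold higher in Sox2 mGS (5.31 ± 0.61, 3530 against 88.8, adjusted p = 6.6e-05), and the matrix protein gene Aspn was higher by 4.17 ± 0.75 (2910 against 161). The proteoglycan gene Srgn (−3.86 ± 0.95, 330 against 4800) and the muscle myosin light chain gene Mylpf (−3.61 ± 0.42, 59.8 against 732) were lower. Naive genes fell: 0 rose, 13 fell and 15 did not pass (2 rose and 16 fell adjusted over the list alone, adjusted p = 3.3e-07, or 0.32 with an estimated correlation), and 6 fell with the feeder score fitted. Esrrb (−2.71 ± 0.72, 359 against 2340) and the AKT co-activator gene Tcl1 (−2.71 ± 0.91) were lower. Feeder and fibroblast genes rose: 14 rose, 0 fell and 7 did not pass (16 rose and 0 fell adjusted over the list alone, adjusted p = 4.9e-06, or 0.59 with an estimated correlation). The matrix genes Postn (3.40 ± 0.88) and Lum (3.32 ± 0.87, 763 against 76.2) were higher, and all 21 members were higher in value. Feeder scores were 1490 in Sox2 mGS and 292 in iPS, and with the score fitted, chosen after the data were seen, 2640 genes passed. In all 4708 genes passed, 2869 higher and 1839 lower (1807 higher and 2445 lower after quantile normalization and 1283 higher and 3003 lower with each array centred on its median). Without iPS 1 the count was 2847, without iPS 2 2908, without Sox2 mGS 3 2420 and with only the groups compared 7845. Srgn lost its call without iPS 1 (−3.03). Esrrb lost its call without Sox2 mGS 2 (−1.96), and Postn without iPS 1 (3.03). Tcl1 lost its call without iPS 1 (−2.44), iPS 2 (−2.59), Sox2 mGS 2 (−2.15) or Sox2 mGS 3 (−2.51).

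Against spontaneous mGS, Lgr5 was higher in Sox2 mGS by 4.04 ± 0.68 (3530 against 214), and the oocyte and ES cell gene Khdc3 was lower (−2.95 ± 0.71). Naive genes fell: 0 rose, 5 fell and 23 did not pass (0 rose and 8 fell adjusted over the list alone, adjusted p = 4.3e-07, or 0.62 with an estimated correlation), and 2 fell with the feeder score fitted. Sox2 itself was among them, as was Dppa5a (−1.68 ± 0.43). Feeder genes were higher as a list: 2 rose, 0 fell and 19 did not pass (8 rose and 0 fell adjusted over the list alone, adjusted p = 5.8e-05, or 0.82 with an estimated correlation). Of these Lox differed by 2.71 ± 0.76 and Fap was under the background in both groups, and feeder scores were 1200 to 1720 against 247 and 804. In all 1539 genes passed, 790 higher and 749 lower (644 higher and 1074 lower after quantile normalization and 478 higher and 1206 lower with each array centred on its median). Without mGS 1 the count was 68, without mGS 2 966, without Sox2 mGS 1 812 and without Sox2 mGS 3 419. Lgr5 lost its call without mGS 1 (2.99). Khdc3 lost its call without mGS 1 (−2.39), Sox2 mGS 2 (−2.73) or Sox2 mGS 3 (−3.14). Dppa5a lost its call without mGS 1 (−1.55), mGS 2 (−1.81), Sox2 mGS 2 (−1.33) or Sox2 mGS 3 (−1.55). Lox lost its call without mGS 1 (1.37), Sox2 mGS 1 (2.67), Sox2 mGS 2 (2.83) or Sox2 mGS 3 (2.62).

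Oct4 mGS lines were compared with ES, iPS and spontaneous mGS to show what the Oct4 route left different. Against ES, Kcnma1 was higher by 4.33 ± 0.31 (688 against 34.1), as in iPS and mGS. Lgr5 was higher by 3.68 ± 0.61 (1470 against 115), and Phf11d was lower (−3.02 ± 0.67, 123 against 999). Naive genes were lower: 0 rose, 2 fell and 26 did not pass (0 rose and 5 fell adjusted over the list alone, adjusted p = 5e-07, or 0.21 with an estimated correlation). They averaged 1090, 831 and 1890 in Oct4 mGS 1, 2 and 3, with feeder scores of 1360, 1060 and 542, and 1860 to 2180 in ES. The members were Zfp42, which encodes Rex1 (−2.18 ± 0.51), and Gdf3 (−0.76 ± 0.22). Germline genes fell: 1 rose, 7 fell and 26 did not pass (2 rose and 12 fell adjusted over the list alone, adjusted p = 0.00011, or 0.31 with an estimated correlation). Tex19.1 (−1.62 ± 0.34) and the piRNA factor gene Tdrd12 (−1.61 ± 0.36) were lower. In all 1875 genes passed, 1289 higher and 586 lower (842 higher and 915 lower after quantile normalization and 530 higher and 1000 lower with each array centred on its median). Without ES BRC1 the count was 931, without Oct4 mGS 1 914, without Oct4 mGS 2 905 and with only the groups compared 159. Phf11d lost its call without Oct4 mGS 2 (−2.45), and Tdrd12 without Oct4 mGS 2 (−1.27). Zfp42 lost its call without ES R1 (−1.77), ES BRC1 (−1.90), Oct4 mGS 1 (−2.05) or Oct4 mGS 2 (−1.82). Gdf3 lost its call without ES B6-6 (−0.83), ES BRC1 (−0.59), Oct4 mGS 1 (−0.81) or Oct4 mGS 2 (−0.55).

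Against iPS, Lgr5 was higher in Oct4 mGS by 4.04 ± 0.61 (1470 against 88.8), and Srgn was lower (−3.37 ± 0.95, 465 against 4800). Naive genes fell: 0 rose, 4 fell and 24 did not pass (adjusted p = 3.5e-09, or 0.19 with an estimated correlation). In iPS they averaged 1760 to 2380, around the 1890 of Oct4 mGS 3. The homeobox gene Gbx2 (−2.11 ± 0.67) and Dppa5a (−1.32 ± 0.38) were lower. Feeder genes rose: 5 rose, 0 fell and 16 did not pass (12 rose and 0 fell adjusted over the list alone, adjusted p = 0.0027, or 0.5 with an estimated correlation). The matrix genes Lum (2.86 ± 0.87) and Dcn (2.73 ± 0.68) were higher, with feeder scores of 921 against 292. Targets of p53 were lower as a list (median −0.33, adjusted p = 3.5e-06, or 0.29 with an estimated correlation), with 914 in Oct4 mGS 1 and 862 in iPS 1. In all 2749 genes passed, 2066 higher and 683 lower (670 higher and 969 lower after quantile normalization and 356 higher and 1246 lower with each array centred on its median), and the median of all genes was 0.119 higher in Oct4 mGS. Without iPS 1 the count was 1136, without iPS 2 934, without iPS 5 1296, without Oct4 mGS 1 971, without Oct4 mGS 2 1203 and with only the groups compared 962. Srgn lost its call without iPS 1 (−2.54), iPS 5 (−3.21), Oct4 mGS 1 (−2.94) or Oct4 mGS 2 (−3.18). Gbx2 lost its call without any 1 line of iPS or Oct4 mGS (−2.33 to −1.90). Dppa5a lost its call (−1.35 to −0.90) without any 1 iPS line, Oct4 mGS 1 or Oct4 mGS 2. Lum lost its call without iPS 1 (2.58), iPS 2 (2.84), iPS 5 (3.18), Oct4 mGS 1 (2.49) or Oct4 mGS 2 (2.74), and Dcn without iPS 1 (2.49), iPS 2 (2.66), Oct4 mGS 1 (2.48) or Oct4 mGS 2 (2.63).

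Against spontaneous mGS, the aggrecan-cleaving protease gene Adamts5 was higher in Oct4 mGS by 2.67 ± 0.62, and Aard was lower (−2.52 ± 0.44). As lists, naive genes (median −0.69, adjusted p = 2.2e-08, or 0.22 with an estimated correlation) and p53 targets (median −0.30, adjusted p = 1.3e-06, or 0.31 with an estimated correlation) were lower. Naive genes averaged 1890 in Oct4 mGS 3 and 1650 in mGS 2. Over all genes, 0 members of either passed limma's adjusted p, and feeder genes did not pass as a list (adjusted p = 0.058). In all 374 genes passed, 237 higher and 137 lower (102 higher and 217 lower after quantile normalization and 51 higher and 201 lower with each array centred on its median). Without mGS 1 the count was 13, without mGS 2 188, without Oct4 mGS 1 146, without Oct4 mGS 2 96, without Oct4 mGS 3 1004 and with only the groups compared 0 (2484 at an unadjusted p under 0.05). Adamts5 lost its call without mGS 1 (1.61), Oct4 mGS 1 (2.42) or Oct4 mGS 2 (2.55), and Aard without mGS 1 (−1.56).

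Each of the 4 vector routes was set against the 9 lines of the other routes, to ask whether the route of derivation left its own pattern. In Dnmt mGS germline genes rose: 15 rose, 2 fell and 17 did not pass (19 rose and 2 fell adjusted over the list alone, adjusted p = 1.9e-08, or 0.28 with an estimated correlation). They averaged 302, 333 and 263 in Dnmt mGS 1, 2 and 3, of which line 2 had unreduced Dnmt1, and 280 in Dmrt mGS 1. Smc1b was higher by 2.64 ± 0.60 (664 against 106), the piRNA factor gene Gtsf1 by 2.62 ± 0.39 (484 against 78.4) and Slc25a31 by 1.95 ± 0.26 (605 against 156). Egr2 (−2.05 ± 0.20, 119 against 494) and the transcription factor gene Myb (−1.84 ± 0.28, 283 against 1010) were lower. Naive genes rose: 10 rose, 3 fell and 15 did not pass (13 rose and 3 fell adjusted over the list alone, adjusted p = 0.00084, or 0.76 with an estimated correlation), and 2 rose and 1 fell with the feeder score fitted. They averaged 1850 to 2300, with 1920 in Dmrt mGS 1 and 1890 in Oct4 mGS 3. Tcl1 was higher by 2.44 ± 0.75 and Tfcp2l1 by 2.28 ± 0.55, while the RNA-binding gene Lin28a fell (−1.01 ± 0.30). Paternally expressed imprinted genes fell: 0 rose, 6 fell and 10 did not pass (1 rose and 9 fell adjusted over the list alone, adjusted p = 0.022, or 0.76 with an estimated correlation, adjusted p = 0.24 with the feeder score fitted), and 2 with the feeder score fitted. They averaged 552 and 465 in Dnmt mGS 1 and 2, 887 in Dnmt mGS 3 and 483 in Dmrt mGS 1. Nnat (−2.26 ± 0.65) was lower. Genes of GDNF and FGF signalling fell: 1 rose, 7 fell and 15 did not pass (3 rose and 13 fell adjusted over the list alone, adjusted p = 0.022, or 0.78 with an estimated correlation, adjusted p = 0.24 with the feeder score fitted), with 592 in Dnmt mGS 3 and 341 in Dmrt mGS 1. Feeder genes were lower (median −1.1, adjusted p = 0.017, or 0.85 with an estimated correlation). In all 3830 genes passed, 1765 higher and 2065 lower (1963 higher and 1525 lower after quantile normalization and 1847 higher and 1179 lower with each array centred on its median). Without Dnmt mGS 1 the count was 542, without Dnmt mGS 2 1488 and with only the groups compared 1835. Smc1b lost its call without Dnmt mGS 1 (2.55), and Tfcp2l1 without Dnmt mGS 1 (1.97). Tcl1 lost its call (2.17 to 2.37) without Dnmt mGS 1 or 2, Dmrt mGS 2 or 3, Sox2 mGS 2 or 3, or Oct4 mGS 1 or 2. Lin28a lost its call without Dnmt mGS 1 (−0.93) or Dnmt mGS 2 (−0.71), and Nnat without Dnmt mGS 1 (−2.17) or Dnmt mGS 2 (−1.62).

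In Sox2 mGS, signalling genes of GDNF and FGF rose: 9 rose, 0 fell and 14 did not pass (10 rose and 0 fell adjusted over the list alone, adjusted p = 7.3e-05, or 0.52 with an estimated correlation). Egr2 was 4.33-fold higher than in the other routes (2.11 ± 0.20, 1040 against 240), and the GDNF co-receptor gene Gfra1 was higher by 1.36 ± 0.20 (659 against 257). The oxysterol enzyme gene Ch25h was higher by 2.78 ± 0.62 (856 against 125) and Il6 by 2.78 ± 0.56 (396 against 57.8), and Elobl was lower (−2.44 ± 0.45, 74.1 against 401). Naive genes fell: 2 rose, 8 fell and 18 did not pass (2 rose and 13 fell adjusted over the list alone, adjusted p = 0.003, or 0.52 with an estimated correlation), and 0 rose and 2 fell with the feeder score fitted. They averaged 1460 in Sox2 mGS 1 and 831 in Oct4 mGS 2. Tfcp2l1 (−1.98 ± 0.55) and Esrrb (−1.87 ± 0.59) were lower. Feeder genes were higher as a list: 2 rose, 0 fell and 19 did not pass (adjusted p = 1.7e-05, or 0.52 with an estimated correlation). Of these the PDGF receptor gene Pdgfrb differed by 1.93 ± 0.57 and Fap was under the background in both groups. Feeder scores were 1200 to 1720, with 1360 in Oct4 mGS 1 and 1180 in Dnmt mGS 3. In all 2822 genes passed, 1195 higher and 1627 lower, and 924 with the feeder score as a covariate. Without Sox2 mGS 1 the count was 1466, without Sox2 mGS 2 1441, without Sox2 mGS 3 532 and with only the groups compared 1596. Ch25h lost its call without Sox2 mGS 3 (2.68), and Tfcp2l1 without Sox2 mGS 2 (−1.66) or Sox2 mGS 3 (−1.83). Esrrb lost its call (−1.88 to −1.12) without Dnmt mGS 1 or 2, Dmrt mGS 1 or 3, or Sox2 mGS 2 or 3. Pdgfrb lost its call (1.78 to 2.21) without Dnmt mGS 1, any 1 Sox2 mGS line or Oct4 mGS 3.

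In Oct4 mGS, germline genes fell: 0 rose, 4 fell and 30 did not pass (1 rose and 8 fell adjusted over the list alone, adjusted p = 1.5e-09, or 0.19 with an estimated correlation). They averaged 155, 160 and 211 in Oct4 mGS 1, 2 and 3, near the background, and 154 to 333 in the other routes. Slc25a31 was lower (−1.29 ± 0.26), and Asz1 was under the background in both groups. The circadian repressor gene Bhlhe41 was higher by 1.44 ± 0.34 (515 against 189). In all 212 genes passed, 162 higher and 50 lower (59 higher and 67 lower after quantile normalization and 17 higher and 28 lower with each array centred on its median). For Oct4 mGS, without Dnmt mGS 1 the count was 88, without Dmrt mGS 1 128, without Dmrt mGS 3 81, without Sox2 mGS 1 66, without Sox2 mGS 3 39, without Oct4 mGS 1 4, without Oct4 mGS 2 16, without Oct4 mGS 3 1008 and with only the groups compared 5. Slc25a31 lost its call (−1.34 to −1.19) without Dnmt mGS 1, Sox2 mGS 1 or 3, or Oct4 mGS 1 or 2. Bhlhe41 lost its call without any 1 line of Dnmt mGS, Sox2 mGS or Oct4 mGS (1.33 to 1.55). In Dmrt mGS, the membrane scaffold gene Flot2 was lower (−0.60 ± 0.10, 681 against 1030). GDNF and FGF signalling genes were lower as a list (median −0.16, adjusted p = 0.0065, or 0.47 with an estimated correlation, adjusted p = 0.23 with the feeder score fitted). They averaged 341 in Dmrt mGS 1 but 652 and 626 in lines 2 and 3. The members that fell were Egr2 (−1.01 ± 0.20) and Egr1 (−0.57 ± 0.10), with 4 adjusted over the list alone. In all 63 genes passed, 29 higher and 34 lower (79 higher and 41 lower after quantile normalization). For Dmrt mGS, without Dmrt mGS 1 the count was 24, without Dmrt mGS 2 7, without Dmrt mGS 3 2, without Sox2 mGS 3 38, without Oct4 mGS 2 41, without Oct4 mGS 3 226 and with only the groups compared 8. Flot2 lost its call without Dmrt mGS 1 (−0.60), Dmrt mGS 2 (−0.60) or Dmrt mGS 3 (−0.60), and Egr1 without Dmrt mGS 1 (−0.54) or Dmrt mGS 3 (−0.51). Egr2 lost its call without any 1 line of the 4 routes other than Dmrt mGS 2 and Oct4 mGS 3 (−1.03 to −0.69). An F test of limma for any difference among the 4 routes called 3971 genes, 19.9% of those tested. Without Dnmt mGS 1 the count was 1997, without Sox2 mGS 3 1918 and with only the groups compared 1711. With the feeder score as a covariate, 1391 genes passed.

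Each line was placed over all genes between the GS mean, set to 0, and a reference mean, set to 1. A position under 1 is not by itself incomplete conversion, as ES lay at 0.902 on the axis to iPS. On the axis to ES, iPS lay at 0.988 (SD 0.019), mGS at 0.976, Dmrt mGS at 0.921 (SD 0.041), Dnmt mGS at 0.910 (SD 0.040), Oct4 mGS at 0.907 (SD 0.025) and Sox2 mGS at 0.892 (SD 0.014). On the axis to iPS, mGS lay at 0.963, ES at 0.902 (SD 0.039), Dmrt mGS at 0.893 (SD 0.025), Dnmt mGS at 0.887 (SD 0.010), Oct4 mGS at 0.866 (SD 0.031) and Sox2 mGS at 0.821 (SD 0.007). The 3 Sox2 mGS lines lay below all lines of each other route on the axis to iPS, with a two-sided exact permutation p of 0.1, the smallest that 3 lines against 3 can give, and 0.4 after Benjamini-Hochberg adjustment over 12 tests. Feeder scores were 1200 to 1720 in Sox2 mGS and 241 to 345 in iPS. Correlations across genes, which are not independent replicates, were 0.848 to 0.892 between GS and other lines and 0.902 to 0.996 among the 20 other lines. The closest pairs crossed the routes in places: mGS 1 with iPS 2 (0.993), Oct4 mGS 2 with Sox2 mGS 2 (0.993) and Dnmt mGS 2 with Dmrt mGS 1 (0.994).

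**Figure D2:**
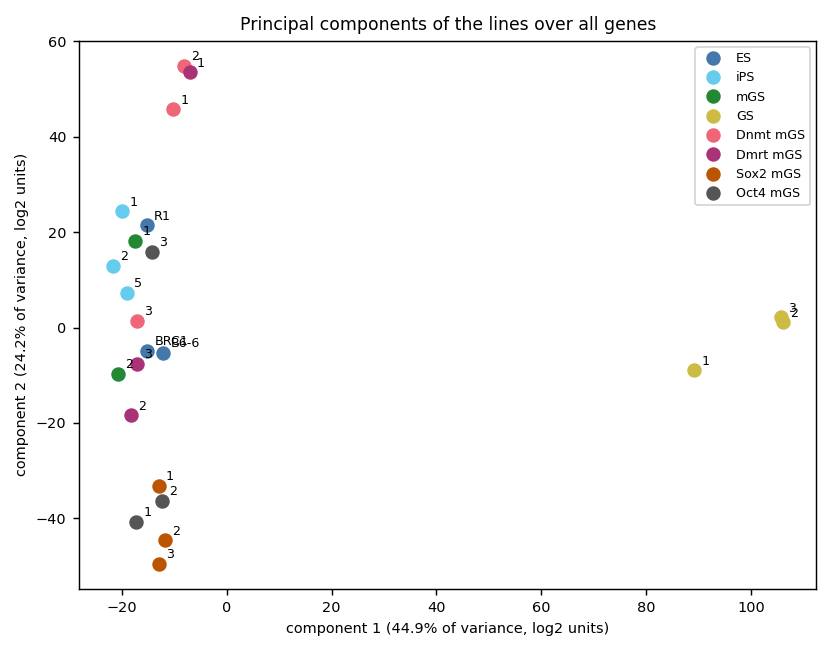
Lines on the first and second principal components of log2 intensity over all genes (44.9% and 24.2% of the variance), 1 point per line, coloured by group. GS lines lie apart at 89 to 106 on component 1, and Dnmt mGS 1 and 2 with Dmrt mGS 1 lie at the opposite end of component 2 from Sox2 mGS.

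Markers of testis somatic cells (116 to 159) and of a 2-cell-like state (78.3 to 127) averaged under the background in all 23 lines and are not described. As a list, GDNF and FGF signalling genes did not pass between GS and ES (adjusted p = 0.8, median −0.19, mean 0.16), as Ret and Gfra1 (3.14 ± 0.25) rose and the feedback inhibitor Spry2 fell (−2.25 ± 0.50). The 4 targeted genes as a list passed only in Dmrt mGS against the other routes (adjusted p = 0.037, or 0.31 with an estimated correlation). Over all 494 tests of a list in a comparison, 172 passed, 27 of them with an estimated correlation.

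**Figure D3:**
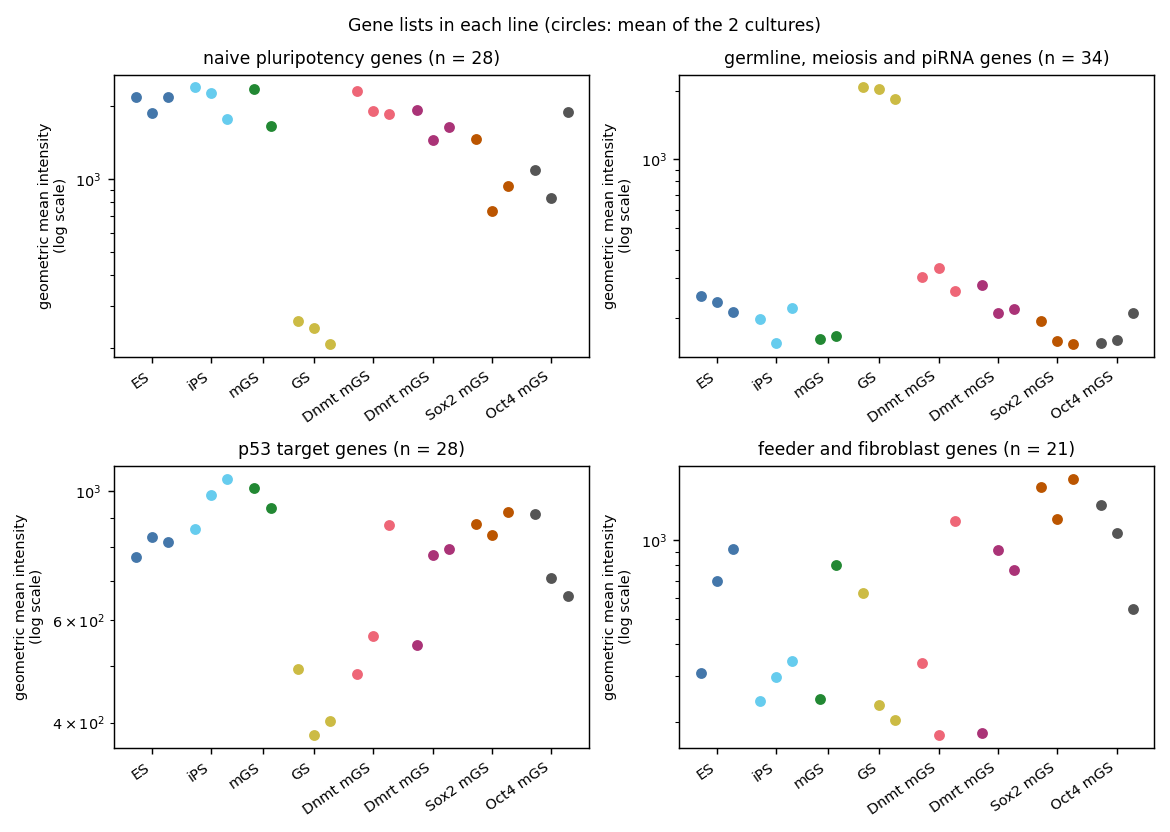
Mean intensity (log axis) of the naive pluripotency, germline, p53 target and feeder gene lists in each of the 23 lines, with circles for the mean of the 2 cultures. Germline genes read 1850 to 2080 in GS, and feeder genes 1200 to 1720 in Sox2 mGS against 241 to 345 in iPS.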

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

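All tests of an explanation in this part were chosen only after the result was seen.

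In GS 1, Sox2 (1810) and Pou5f1 (1000) stood above GS 2 and 3 (331 and 293, and 365 and 381). Pluripotent cells mixed into the culture would bring their other genes, but over 19 genes that ES hold far above GS, the median share of the ES level that GS 1 reached was 0.772%, where Pou5f1 would need 16.3% and Sox2 40.2%. A single aberrant culture is argued against as well, since Sox2 was 1670 in the lower culture of GS 1 and at most 377 in any culture of the other GS lines. A state of the line itself stays open, and no biological explanation was tested.

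The line labelled Dnmt mGS 2 had 2750 of Dnmt1, against 620 and 647 in the other lines of its route. A label swapped with a line of another route would leave a low Dnmt1 there, but the lowest of those 9 lines was 1930. A line of another route that carries a Dnmt mGS label cannot be told apart from one whose knockdown was lost or weak. The line closest to Dnmt mGS 2 was Dmrt mGS 1 (r = 0.994 across genes), with 0.986 for Dnmt mGS 1 and 0.953 for Dnmt mGS 3. Lines of different routes resembled each other elsewhere. Eif2s3y was 27.6 in Dnmt mGS 2, 31 in Dnmt mGS 1 and 371 in Dmrt mGS 1. It was also low in mGS 1 (45.1), so it does not decide. Loss of the knockdown was not tested.

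Feeder and fibroblast genes were higher in Sox2 mGS than in iPS. An array-wide scale is argued against, since their median difference was 2.17 with centred arrays. The list cannot tell carried feeder cells from mesenchymal differentiation, which was not tested: 21 of 21 members were higher, as either gives. Xist read 480 to 796 in Sox2 mGS and 109 to 229 in iPS, but the feeders' sex is not given.

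Single cultures far from the other 5 of their group (3 in mGS) were found in 13 of 176 groups tested. Chance gives about 9, or 1 in 20, for unrelated arrays, which 2 cultures of a line are not. Of these, 5 came from culture 1 of Oct4 mGS 1: its array median was 264.8 (others 227.3 to 237.6), Dnmt1 2420 (1920 to 2030), Pou5f1 5690 (4570 to 4840), the 2-cell-like list 64.8 (89.3 to 101) and the GDNF and FGF list 723 (577 to 622). Pou5f1 was 4760 in culture 1 of Sox2 mGS 1 (others 4140 to 4330). Germline genes averaged 159 in culture 1 of mGS 1 (others 166 to 167). Trophoblast genes averaged 338 in culture 2 of iPS 5 (239 to 248) and 218 in culture 1 of Dnmt mGS 2 (239 to 244). Proliferation genes averaged 2360 in culture 1 of ES BRC1 (2540 to 2650). In culture 1 of iPS 5, G1 and Myc genes averaged 743 (827 to 868) and glycolysis genes 3320 (2830 to 2990). Glycolysis genes averaged 2610 in culture 1 of Dmrt mGS 3 (2470 to 2530).

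Against the other routes, Dnmt mGS gave 3830 genes, Dmrt mGS 63, Sox2 mGS 2822 and Oct4 mGS 212, with Dnmt1 at −1.07 in Dnmt mGS and Sox2 at −1.50 in Sox2 mGS. Of the 5446 probe sets outside the annotation, 2000 passed adjusted p in GS against ES, 871 higher and 1129 lower in GS, and of the 1621 with several gene symbols 619 passed, 217 higher and 402 lower.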

How the results depend on the processing

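The feeder covariate and leaving out culture 1 of Oct4 mGS 1 were chosen after the results were seen. Counts against GS were within 1.5 times the reported count under every setting but the clone number, and without any single line. All 27 counts were within 1.5 times with eBayes and a trend and with the probe sets of a gene averaged, 25 without the 40% dimmest genes, 24 with quantile normalization and 23 with each array centred on its median. For counts that moved further, some settings took away lines or genes, or added residual degrees of freedom, by construction; for the others the cause was not tested. A change in a gene near the background can be hidden.

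Leaving out 1 line at a time took away samples and moved all counts but those of comparisons with GS. The lowest and highest counts, with that of all lines in brackets, were, against ES, 40 to 900 (125, iPS), 14 to 202 (41, mGS), 1002 to 2909 (2263, Dnmt mGS), 308 to 1026 (929, Dmrt mGS), 1433 to 2580 (2948, Sox2 mGS) and 905 to 2672 (1875, Oct4 mGS). Against iPS they were 0 to 2 (0, mGS), 279 to 1859 (1369, Dnmt mGS), 17 to 106 (169, Dmrt mGS), 2420 to 3550 (4708, Sox2 mGS) and 934 to 3614 (2749, Oct4 mGS). With mGS as reference they were 29 to 1109 (544, Dnmt mGS), 0 to 9 (13, Dmrt mGS), 68 to 1030 (1539, Sox2 mGS) and 13 to 1004 (374, Oct4 mGS). Each route against the rest gave 542 to 5434 (3830, Dnmt mGS), 2 to 226 (63, Dmrt mGS), 532 to 3555 (2822, Sox2 mGS) and 4 to 1008 (212, Oct4 mGS), with 1918 to 5242 (3971) among the 4 routes. Positions on the GS to ES axis ranged over 0.927 to 0.984 (0.976, mGS), 0.856 to 0.919 (0.91, Dnmt mGS), 0.867 to 0.912 (0.892, Sox2 mGS), 0.876 to 0.918 (0.907, Oct4 mGS) and 0.928 to 1.003 (0.988, iPS). Positions on the GS to iPS axis ranged over 0.947 to 0.969 (0.963, mGS), 0.874 to 0.897 (0.887, Dnmt mGS) and 0.796 to 0.847 (0.821, Sox2 mGS). Without 1 of the 2 spontaneous mGS lines, the lone line was assumed to vary like the other groups. Of 182 named calls, 116 passed without every line in turn.

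With all 46 arrays taken as independent samples, which treats 2 cultures of a line as unrelated, all 27 counts were higher; those over 1.5 times were, against ES, 2318 (iPS), 804 (mGS), 6136 (Dnmt mGS), 3947 (Dmrt mGS), 6768 (Sox2 mGS) and 5666 (Oct4 mGS). Against iPS they were 6 (mGS), 5189 (Dnmt mGS), 3930 (Dmrt mGS), 9162 (Sox2 mGS) and 7926 (Oct4 mGS). Against mGS they were 4198 (Dnmt mGS), 1418 (Dmrt mGS), 5911 (Sox2 mGS) and 4197 (Oct4 mGS). Against the other routes they were 8946 (Dnmt mGS), 1741 (Dmrt mGS), 7319 (Sox2 mGS) and 3365 (Oct4 mGS), with 10719 among the 4 routes. Of the 188 named values, 186 kept their side of the threshold and 2 gained a call.

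With only the lines of the groups compared in the fit, which takes away samples, 22 counts were lower; those that moved were, against ES, 22 (iPS), 2 (mGS), 330 (Dnmt mGS), 0 (Dmrt mGS) and 159 (Oct4 mGS). Against iPS they were 1 (mGS), 881 (Dnmt mGS), 7 (Dmrt mGS), 7845 (Sox2 mGS) and 962 (Oct4 mGS). With mGS as reference they were 4 (Dnmt mGS), 0 (Dmrt mGS) and 0 (Oct4 mGS). Each route against the rest gave 1835 (Dnmt mGS), 8 (Dmrt mGS), 1596 (Sox2 mGS) and 5 (Oct4 mGS), with 1711 among the 4 routes. Here 140 named values kept their side of the threshold and 48 lost their call.

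With quantile normalization, the counts that moved were, against iPS, 1639 (Oct4 mGS). Against the other routes they were 120 (Dmrt mGS) and 126 (Oct4 mGS). On the GS to ES axis, the position was 0.97 (mGS). On the GS to iPS axis, positions were 0.974 (mGS), 0.899 (Dnmt mGS) and 0.849 (Sox2 mGS). Here 183 named values kept their side, 4 lost a call and 1 gained one. Centring each array gave, against iPS, 351 (Dmrt mGS) and 1602 (Oct4 mGS). Against mGS it was 20 (Dmrt mGS). Each route against the rest gave 45 (Oct4 mGS). It left 184 named values on their side and 4 without a call. Without the 40% dimmest genes, the counts that moved were, against iPS, 1753 (Oct4 mGS). Against mGS it was 8 (Dmrt mGS). On the GS to ES axis, the position was 0.979 (mGS). On the GS to iPS axis, positions were 0.898 (Dnmt mGS) and 0.83 (Sox2 mGS). Of 170 named values left, 169 kept their side and 1 gained a call. Without culture 1 of Oct4 mGS 1, 8 of 9 counts stayed within 1.5 times, and Oct4 mGS against the other routes gave 108.

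On the 20% of genes with the highest variance, the median correlation between lines was 0.346 for GS with the other types and 0.85 among the others. Positions on the GS to ES axis became 0.984 (mGS), 0.916 (Sox2 mGS) and 0.933 (Oct4 mGS). Those on the GS to iPS axis became 0.974 (mGS), 0.903 (Dnmt mGS), 0.852 (Sox2 mGS) and 0.897 (Oct4 mGS). With the correlation in each list estimated, 27 of the 172 list results passed. Without the dimmest genes 129 passed, 123 of them among the 172, and with the feeder score 164 and 132.

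With the feeder score as a covariate, 13 of 27 counts stayed within 1.5 times; the others were, against ES, 361 (iPS) and 94 (mGS). Against iPS they were 1 (mGS), 3272 (Dnmt mGS), 889 (Dmrt mGS) and 2640 (Sox2 mGS). Against mGS they were 1478 (Dnmt mGS), 51 (Dmrt mGS), 928 (Sox2 mGS) and 739 (Oct4 mGS). Against the other routes they were 1672 (Dnmt mGS), 103 (Dmrt mGS) and 924 (Sox2 mGS), with 1391 among the 4 routes. Of named values 165 kept their side, 21 lost their call, 1 gained one and 1 changed sign (Cdh11 in Sox2 mGS against GS, −0.11). The cause was not tested.

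The numbers of cultures and clones do not pair the samples. Differences between 2 cultures correlated between lines with a median r of 0 (−0.44 to 0.39, 72 of 253 over 0.1), and deviations of clones with 0.08 (−0.64 to 0.79, 24 of 52). With all 46 arrays and the line as a random block (correlation between cultures 0.645), the counts that moved were, against ES, 650 (iPS), 237 (mGS), 3624 (Dnmt mGS), 1853 (Dmrt mGS) and 3037 (Oct4 mGS). Against iPS they were 1 (mGS), 2788 (Dnmt mGS) and 758 (Dmrt mGS). With mGS as reference they were 2120 (Dnmt mGS), 189 (Dmrt mGS), 2939 (Sox2 mGS) and 1182 (Oct4 mGS). Each route against the rest gave 368 (Dmrt mGS), 4714 (Sox2 mGS) and 919 (Oct4 mGS), with 6225 among the 4 routes. With that block, 191 lists passed, 167 of them among the 172. Those that moved with culture number as a replicate block were, against ES, 632 (iPS), 208 (mGS), 3584 (Dnmt mGS), 1822 (Dmrt mGS) and 2988 (Oct4 mGS). Against iPS they were 1 (mGS), 2741 (Dnmt mGS) and 738 (Dmrt mGS). Against mGS they were 2094 (Dnmt mGS), 187 (Dmrt mGS), 2894 (Sox2 mGS) and 1169 (Oct4 mGS). Against the other routes they were 347 (Dmrt mGS), 4659 (Sox2 mGS) and 910 (Oct4 mGS), with 6177 among the 4 routes. In both, 186 named values kept their side and 2 gained a call. Clone number as a replicate block, fitted on the groups compared alone, gave no value against ES, whose lines have no clone number; the counts that moved were, against iPS, 6611 (GS), 0 (Dmrt mGS) and 4663 (Oct4 mGS). Against GS it was 4530 (mGS). With mGS as reference they were 0 (Dmrt mGS), 0 (Sox2 mGS) and 0 (Oct4 mGS). Each route against the rest gave 1479 (Dnmt mGS), 2 (Dmrt mGS), 1029 (Sox2 mGS) and 0 (Oct4 mGS), with 923 among the 4 routes. Of 116 named values 84 kept their side and 32 lost their call.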

Other observations

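The groupings of lines, genes and gene sets in the first paragraphs of this part were chosen after the values were seen, and the counts over other splits of the lines were planned.

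Myc, a growth regulator that the iPS route supplied as a transgene, was low in some induced lines: 55.4 in Dnmt mGS 2, 69.6 in Dmrt mGS 1, 192 in Dnmt mGS 1 and 228 in Oct4 mGS 3, against 96.2 to 227 in GS and 484 to 1600 in all other lines. Dnmt mGS 1, Dnmt mGS 2 and Dmrt mGS 1 also had the lowest means of GDNF and FGF signalling genes in their routes (388, 337 and 341, against 592, 652 and 626 in Dnmt mGS 3, Dmrt mGS 2 and Dmrt mGS 3). Their p53 targets averaged 484, 563 and 544, against 875, 777 and 794 in the same other lines, and their primed genes 307, 267 and 268, against 478, 637 and 547. Germline genes averaged 302, 333 and 280 in them, against 263, 211 and 218, and feeder scores were 337, 179 and 182, against 1180, 918 and 770.

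Y-linked genes differed by line. Eif2s3y and Uty read 45.1 and 31.4 in mGS 1, 31 and 28.8 in Dnmt mGS 1 and 27.6 and 30 in Dnmt mGS 2. Zfy1 was 19.2 to 24.1 there, 20 to 27.9 in Sox2 mGS, 19.9 in Dnmt mGS 3 and 34.5 and 22.8 in Oct4 mGS 1 and 2. It was 48.9 to 1140 in others, so low Zfy1 was not confined to 1 route. Uty was 57.4 to 990 in others. Eif2s3y was 1330 in Oct4 mGS 3, 107 to 733 in other lines of the 4 routes and 739 to 2210 elsewhere. Kdm5d was 768 to 1500 in ES and GS, 780 in Oct4 mGS 3 and 134 to 257 elsewhere (background 161). In genes of at least 9 mean log2 intensity grouped into 20 chromosome-sized sets of neighbours (6392 genes), ES R1 was higher by 0.27 than the other lines outside GS in the set that holds Mt1 and by 0.27 in the set that holds Stat3, against −0.06 to 0.01 in the other 18 sets. All other lines and sets lay between −0.17 and 0.17.

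The number of genes called was recounted over other splits of the same lines. For 3 lines against 3, the 10 splits are too few for a share under 0.05, and the real split, 1 of 10, stood beside a highest other count of 15 for GS against ES (8611), 0 for GS against iPS (10769) and 1 for iPS against ES (125). Against GS, the highest other count was 0 for Dnmt mGS (9797), 30 for Dmrt mGS (8303), 3 for Sox2 mGS (8776) and 42 for Oct4 mGS (8545). Against ES, it was 818 for Dnmt mGS (2263), 11 for Dmrt mGS (929), 0 for Sox2 mGS (2948) and 1 for Oct4 mGS (1875), and against iPS it was 0 for each of the 4 (1369, 169, 4708 and 2749), by limma's adjusted p.

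Against the other routes, 100 splits were drawn. Unadjusted for the 5 tests, the share was under 0.05 for Dnmt mGS (3830, reached by 2 splits, highest other 6083). It was too for Sox2 mGS (2822, reached by 3, highest other 3360) and the F test (3971, reached by 1, highest other 3916). It was not for Dmrt mGS (63, reached by 7 splits, highest other 2077) or Oct4 mGS (212, reached by 7, highest other 5843). These shares do not exclude chance. Splits with higher counts point to a structure of the lines that the routes do not follow. For Dnmt mGS and Oct4 mGS the highest set Dnmt mGS 1, Dnmt mGS 2 and Dmrt mGS 1 against the rest.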
